A study of Mus musculus with 5 samples.

How the data were processed

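Gene expression was measured on 2-colour custom Agilent mouse oligonucleotide arrays, in which a laser-dissected mammary sample and a common reference RNA were hybridised together. Per the labels' protocols, RNA from dissected cells (5000 per frozen block) was amplified in 2 rounds, and 825 ng of amplified RNA was labelled with Cy3. The reference, labelled with Cy5, was a pool of adult male mouse RNA made of 30% testis, 30% liver, 30% kidney and 10% prostate. Agilent Feature Extraction is named in the submitters' processing notes, with no version. The background correction, the normalization and the filters are not given in the sources used here.

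The authors deposited 1 value per array feature and array, which is taken here as a log2 ratio of the 2 channels. The log base and the numerator are not stated, so differences are given in log2 units and not as folds. The base rests on the range of the values (from -9.70 to 9.59), which is too wide for log10 of a scanner ratio and does not exclude natural logarithms. The scale was kept as deposited: the array medians were 0.01, 0.11, 0.15, 0.08 and 0.11 for control arrays 1 and 2 and the tumours of mice 4, 6 and 12. Each array's median was also its most common exact value, referred to below as the shared value, and no other exact value occurred on more than 2 features of an array. The shared value is read here as the ratio of features whose channels had both been set to a common floor, which is an inference from the values. Intensities were not used here, so a feature with only 1 channel near background is not recognised, and signal over background limits the precision by an unknown amount.

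The table names its rows by feature number (up to 45220) and has no gene column, and no table pairing these numbers with genes was used here. The 27 gene lists fixed before the data were examined, the check of the Erbb2 gene and the rule naming 8 genes per direction were therefore not run. In their place every feature was tested by itself, and the 2 features with the largest rise and the 2 with the largest fall are named, among those with adjusted p under 0.05 and all 3 tumours on one side of both control arrays. This shortened rule was set after the table had been seen to lack gene names. A gene can be represented by several features, and counts of features are not counts of genes.

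Both control arrays carry a pool of the same 2 control mice according to their labels, and only 2 control mice are described for the study. They were averaged and counted as 1 sample. The main comparison therefore set 3 tumours, each from its own mouse, against 1 control sample. Features measured on all 5 arrays were fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3. Tests were two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The fit had 2 residual degrees of freedom, to which the moderation added 1.83, and it assumes that the lone control sample varies as the tumours do. Variation between control mice was not measured. All arrays had the sample in the same dye, so a constant dye bias of a feature cancels in the difference between groups. The labels give no slide or scan batch. Figures were drawn with matplotlib 3.10.9.

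The fit was tested on simulated data for this comparison, with 41609 features. Unchanged features had an unadjusted p under 0.05 in 5.02% of cases. With 200 features changed, 0 of the 67 changed by 1 log2 unit, 0 of the 67 changed by 2 and 0 of the 66 changed by 4 passed the adjusted threshold, although 82.1%, 91.0% and 97.0% of them had an unadjusted p under 0.05. With 5000 features changed by 2 log2 units, 77.0% were called, with 173 false calls. The simulated errors were normal and independent, with variances drawn from the prior that limma had fitted to these data. The simulated control varied as the tumours did, and no feature was tied at a shared value. A rate near the nominal one was thus built in, and the simulation cannot show whether calls in the real data are calibrated.

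Alternatives set before the data were examined were the 2 control arrays as separate samples, each array left out in turn, median centring, quantile normalization, a looser rule on missing values, a limit of 1 log2 unit on the difference between control arrays, robust moderation, an adjusted p under 0.10 and limma's treat test against 1 log2 unit. Alternatives added after the values were seen left out features at the shared value, centred each array on it, or changed the distance from it.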

Results

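The transcriptome of mammary tumours was profiled in a doxycycline-inducible mouse model of Her2/Neu breast cancer and compared with benign mammary epithelium. In this model an MMTV-driven reverse tetracycline transactivator switches on NeuNT, an activated form of the Neu (Erbb2) receptor tyrosine kinase, in mammary epithelium when doxycycline is given. The tumours came from 3 bitransgenic FVB females, numbered 4, 6 and 12. The control was a pool of epithelium from 2 littermates that carried the responder transgene alone, hybridised on 2 arrays. All animals drank doxycycline (2 mg/mL) from 8 weeks of age, and tumours were collected at about 1.0 cm. The deposited table held 42591 array features, of which 41609 were measured on all 5 arrays. Missing values were most frequent on control array 1, with 614 features, against 153 on control array 2 and 79 to 143 on the tumour arrays. The features carry numbers and no gene names, so the results below describe array features and neither the Neu transgene nor any gene or pathway could be read out.

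The first question was which way the deposited ratios run. On each array 4090 to 5679 features (9.74% to 13.4% of those measured) had exactly the same value, and 2206 features had it on all 5 arrays. Features that sat at this shared value on all 3 tumour arrays and more than 1 log2 unit away from it on both control arrays numbered 213. Of these, 211 (99.1%, exact binomial 95% interval 96.6% to 99.9%) lay above it on both control arrays and 0 lay below on both. In the opposite case, at the shared value on both control arrays and away from it on all 3 tumours, 12 of 13 features lay above. Since the reference RNA was common to all arrays, the dissected sample is likely the numerator. The intervals cover counting only, since features are not independent. Higher and lower below refer to the deposited ratio; with the opposite numerator every direction would turn.

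The second question was how closely arrays of 1 group agreed. The error of the comparison between groups comes from the 3 tumours alone, because the control arrays were averaged, so a difference between the control arrays does not enter it. Across features, which are not independent replicates, Pearson's r was 0.953 for the tumours of mice 4 and 6, 0.966 for each of the other tumour pairs and 0.945 for the 2 control arrays of the same pool. By Spearman's rho the control pair, at 0.936, lay within the 0.910 to 0.937 of the tumour pairs. Between control and tumour arrays r ranged from 0.791 to 0.856 and rho from 0.741 to 0.794. The SD of the difference between arrays was 0.69 log2 units for the control pair, 0.53 on average for tumour pairs and 1.18 on average between the groups. The larger SD of the control pair came from the features that differed most: its median absolute difference was 0.21, within the 0.19 to 0.27 of the tumour pairs, while 4754 features differed by more than 1 log2 unit between control arrays, against 2325 to 3441 between tumours. Control array 1 lay farther from each of the 3 tumours (SD 1.24 to 1.32) than control array 2 did (1.06 to 1.11).

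**Figure D1:**
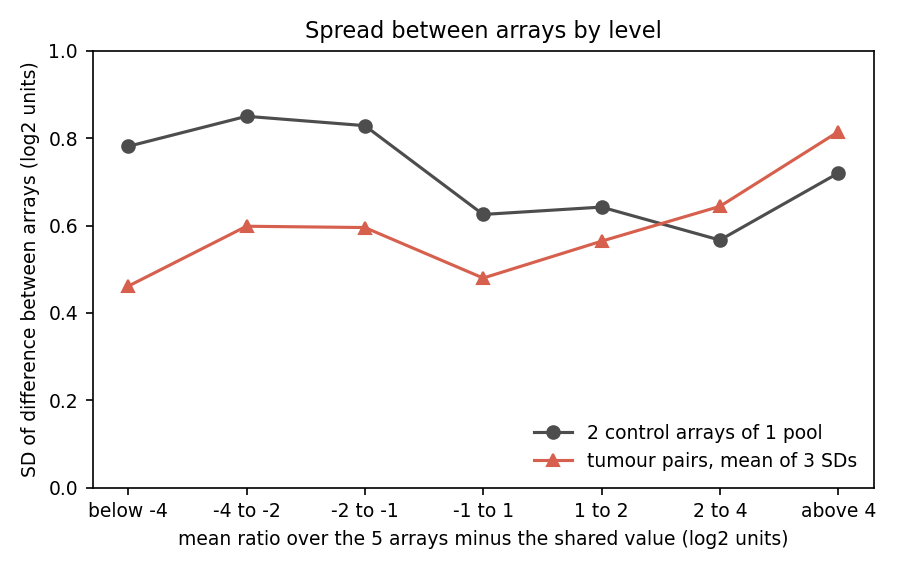
SD of the difference between arrays (log2 units, vertical axis) for features grouped by their mean ratio over the 5 arrays relative to the shared value (log2 units, horizontal axis), for the 2 control arrays (circles) and as the mean over the 3 tumour pairs (triangles). The control pair had the larger SD among features more than 4 log2 units below the shared value (0.78 against 0.46) and the smaller SD among those 2 to 4 units above it (0.57 against 0.64).

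The main comparison asked which features distinguished tumours from benign epithelium. In tumours 2803 features were lower and 1896 were higher than in the control pool (limma, adjusted p under 0.05), together 11.3% of the 41609 tested. The median change of the features called lower was -2.14 log2 units and that of the features called higher was 1.42. All 3 tumours lay below both control arrays for 2566 of the features called lower and above both for 1820 of those called higher. Of the features called lower, 989 had a mean ratio above 0 in the control and below 0 in the tumours, and 719 of those called higher had the reverse. Before adjustment 13212 features (31.8%) had p under 0.05 in the moderated limma test. Tumours and control arrays did not overlap for 52.2% of the features tested. Chance gives 20% if the 5 arrays are independent samples and at most 50% if the control arrays are 1 sample. The 50% holds for a single control value and is an upper limit, since all tumours had to lie beyond both control arrays. This share by itself therefore cannot tell how far the groups separate. The median difference over all features was 0.05 log2 units. This is the difference of features at the shared value on all 5 arrays, so it reflects the scaling of the arrays, and it was 0 under median centring. A single feature had a median standard error of 0.23.

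Leaving out a tumour takes residual degrees of freedom from the fit, so fewer calls there cannot be credited to that tumour. The count of calls differed with the arrays that entered. It was 4699 with all arrays, 2372 without the tumour of mouse 4, 1680 without that of mouse 6 and 2993 without that of mouse 12. It was 8508 with control array 1 as the only control and 3069 with control array 2 alone, and 8769 when the 2 control arrays were counted as separate samples. Of the 4699 calls, 1158 (24.6%) were on features whose control arrays differed by more than 1 log2 unit, against 11.4% of the features tested, and a fit without such features made 3124 calls.

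Large differences were more often decreases. Tumours were lower by more than 2 log2 units for 2068 features and higher by as much for 565, a ratio of 3.66. Beyond 4 log2 units the numbers were 426 and 72. Against the control pool there were 2113 lower and 618 higher features for mouse 4, 2277 and 809 for mouse 6, and 2204 and 677 for mouse 12; these 3 comparisons share the control values, so they do not replicate the imbalance independently. With control array 1 alone the count of features higher by more than 2 units rose to 1157, and the ratio was 2.32. At more than 3 log2 units above the shared value, 2596 features stood on control array 1 and 1786 on control array 2, against 1140 to 1291 on the tumour arrays. At more than 3 units below it the arrays were closer, with 4304 and 3932 features on the control arrays and 4020 to 4204 on the tumour arrays.

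**Figure D2:**
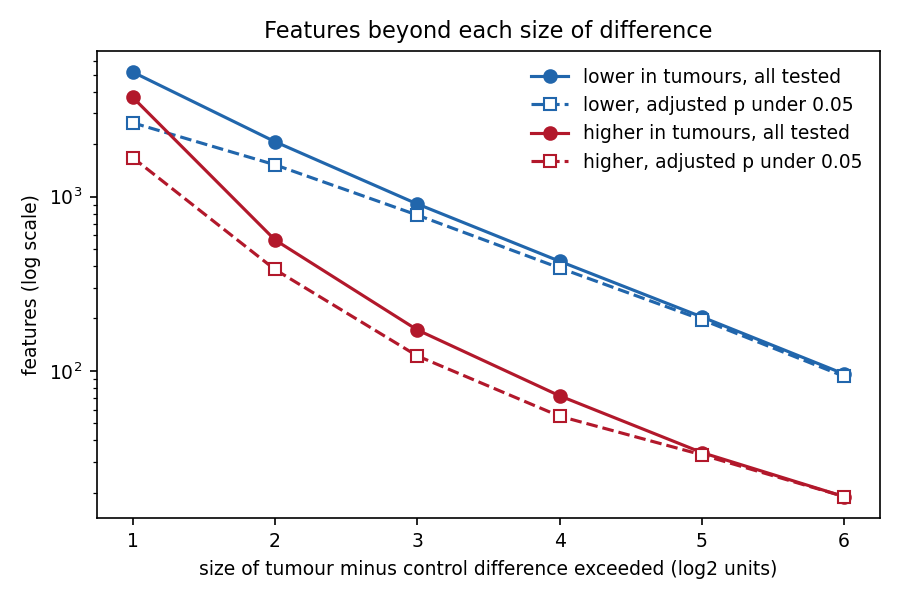
Number of features (vertical axis, log scale) whose tumour minus control difference exceeded each size in log2 units (horizontal axis), for decreases (blue) and increases (red), over all features tested (filled circles) and over those with adjusted p under 0.05 (open squares). Decreases outnumbered increases at each size, with 5192 against 3721 features beyond 1 log2 unit and 96 against 19 beyond 6.

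Some calls involved features at the shared value. Among the features called lower, 484 were at the shared value on all 3 tumour arrays. Both control arrays lay more than 0.5 log2 units above it for 258 of these, whose fall is known only as a lower limit. For 224 only control array 1 did, and 188 of the 484 were at the shared value on control array 2 as well, so that these calls rest on control array 1. Among the features called higher, 53 were at the shared value on all 3 tumour arrays, and both control arrays lay more than 0.5 units below it for 8 of them. Only control array 1 did for 38 and only control array 2 for 7. A control array was at the shared value as well for 43 of the 53, so most of these calls rest on a single control array. Where all 3 tumours were at the shared value, their values differ only by the scaling of the arrays. The standard errors of such calls (median 0.15) therefore come mostly from the moderation, whose prior SD of 0.18 log2 units was fitted over all features. They do not measure the spread of these features between tumours. A further 9 features called higher were at the shared value on both control arrays. The 213 features at the shared value on all tumours and more than 1 log2 unit from it on both control arrays had a median ratio 2.74 log2 units from it on the control arrays. The 13 features in the opposite case had a median of 3.29 on the tumour arrays.

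The 4 features with the largest changes were chosen among those called with all 3 tumours on one side of both control arrays. Feature 35487 had a mean ratio of 4.69 in the control pool, whose arrays differed by 0.03, and -6.17 ± 1.25 (SD, n = 3) in tumours. Its difference was -10.87 ± 1.05 log2 units (SE; limma adjusted p = 0.0194). Feature 30718 fell from 2.99, with control arrays 0.62 apart, to -7.44 ± 0.76 (SD, n = 3), a difference of -10.43 ± 0.65 (SE; limma adjusted p = 0.0106). Feature 32740 had ratios of -1.41 and 0.11 on control arrays 1 and 2, the latter being the shared value, and 7.70 ± 0.78 (SD, n = 3) in tumours. Its fitted difference of 8.35 ± 0.66 (SE; limma adjusted p = 0.0144) is therefore not a measured size; against control array 2 alone it was 7.58, which is a lower limit. Feature 16598 rose from -4.80, with control arrays 0.65 apart, to 3.15 ± 0.90 (SD, n = 3), a difference of 7.94 ± 0.77 (SE; limma adjusted p = 0.0194). The ratios of features 35487 and 30718 in tumours and of feature 16598 in the control lay far below the shared value. Whether the sample channel was at the floor there was not tested, so these differences may be lower limits too. The difference of feature 16598 kept its size but missed the threshold under median centring and under quantile normalization. That of feature 35487 also kept its size, at -10.51 under quantile normalization and -10.53 without the tumour of mouse 6, and missed the threshold in both.

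**Figure D3:**
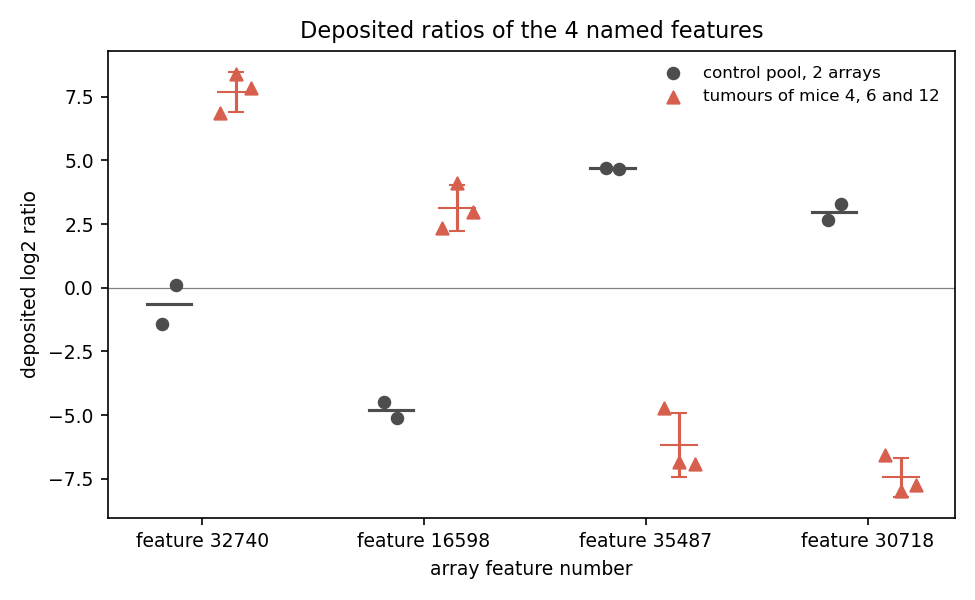
Deposited log2 ratios (vertical axis) of the 4 named features (horizontal axis, array feature number) on the 2 control arrays (circles, with their mean as a line) and in the 3 tumours (triangles, with mean and SD). The mean differences were 7.94, -10.87 and -10.43 log2 units for features 16598, 35487 and 30718. These may be lower limits too, since a sample channel at the floor was not tested for. For feature 32740, with control array 2 at the shared value, the difference from that array was 7.58, a lower limit.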

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

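The 1896 features higher and 2803 lower became 4395 and 4374 with the 2 control arrays as separate samples, 4623 and 4724 at an adjusted p under 0.10, and 122 and 809 under the treat test against 1 log2 unit. They fell to 1240 and 1884 where the control arrays had to agree within 1 log2 unit. Leaving out 1 array gave 369 to 4133 higher and 1311 to 4375 lower features: the fewest without the tumour of mouse 6, the most without control array 2. Features higher by over 2 log2 units ranged from 531 to 1157 when 1 array was left out; those lower by as much stayed within 1.5 times of 2068 in every setting. The cause of these moves was not tested, beyond the changed threshold or number of samples or features that a setting itself brings. The settings with a single control array change none of these, and their error comes from the tumours alone. Their moves therefore come from the values of the control arrays, whose spread the error does not include. Why the control arrays differ was not tested. Median centring, quantile normalization, the looser missing-value rule, robust moderation and leaving out features at the shared value kept both counts within 1.5 times. Similar counts did not mean the same calls. Of the main calls, 59.5% recurred under quantile normalization, 88.2% under robust moderation and 99.96% under the looser rule. The share was 93.2% without features at the shared value on all arrays. It was 76.2% without those at it on any array, where calls on such features could not recur. Median centring equals centring on the shared value: it gave 1861 and 2609, of which 3091 calls in all were shared with the 4699. The share of calls that were higher was 40.3%, and 41.6% under median centring and 49.4% under quantile normalization. No called feature shared with the main setting changed direction, except 1 with control array 1 alone. The share above the shared value was 94.7% at over 0.5 log2 units and 100% at over 2 and over 3 for features at that value in all tumours, and 73.7% (14 of 19, 5 below) at over 0.5 and 100% at over 2 and over 3 for those at it in both controls. The SD ratio of control to tumour pairs was 1.29, and 1.16 without features at the shared value. The 4 named features kept their direction wherever they were tested. The Erbb2 result, the gene list results and the joining of features of 1 gene were not run for want of gene names, and the sign was not turned. The random block for the pool was tried, but its correlation could not be estimated from 5 arrays in 4 blocks. No paired analysis was possible because the groups share no replicate numbers.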

Other observations

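Median centring, quantile normalization, the omission of each control array and the comparison of spread between arrays were set before the data were examined; the other tests in this part were chosen after the main counts had been seen, and for the test of weak signals, the count of splits, the positions of missing values and the correlations between neighbours no outcome was predicted beforehand.

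The excess of large decreases over large increases in tumours is the pattern most open to follow-up once the features are named. Other scalings did not remove it: the lowest ratio of features lower to features higher by more than 2 log2 units was 2.79, under quantile normalization, against 3.66 as deposited. A single aberrant control array is argued against by the ratio of 2.32 with control array 1 alone and 3.54 with control array 2 alone. Features at the shared value or not repeatable do not account for it. The ratio was 3.56 (1501 against 422) among the 31022 features with no shared value and control arrays within 1 log2 unit of each other. A sample channel near the floor stays open. Among the 8680 features more than 0.5 log2 units above the shared value on all arrays the ratio was 1.81 (174 against 96). Its exact binomial 95% interval, 1.41 to 2.35, does not exclude the bound of 1.5. That interval covers counting only, since features are not independent, and it leaves out variation between mice. This selection removes falls that end, and rises that start, below its limit, so the lower ratio cannot decide the question. A loss of transcripts in tumour cells, and cells of other types in the dissected benign epithelium, may each give an excess of large decreases. Without gene names neither was tested.

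The 2 control arrays of 1 pool differed more, by SD, than tumours of different mice (ratio 1.29), though not by median absolute difference. A shift shared by most features of a block is argued against: the ratio was 1.287 after the median of each of 140 blocks was removed. The layout of 532 rows and 85 columns was inferred from the feature numbers. Neighbouring features correlated at no more than 0.0328 in the difference between control arrays. Neither value can exclude a defect in a small patch, since a block median leaves it in place and the correlation runs over all features. Weak signal in the sample channel stays open. The ratio was 1.025 among features more than 1 log2 unit above the shared value and 1.48 among those as far below. This goes with weak signals but misses a bound of 1, which was chosen after the values had been seen. Among features 2 to 4 log2 units above the shared value the ratio was 0.88, so the outcome depends on the cut. Whether the 2 arrays came from separate dissections or amplifications is not given in the sources used here, and a difference between these could also contribute.

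Missing values on control array 1 were not spread evenly: 159 of the 614 lay in the first 10% of the inferred rows, or 25.9% where 10.2% of the features lie. Missing features 170 numbers apart, or 2 inferred rows, correlated at 0.204. The tumour minus control difference correlated at 0.00467 between adjacent features and at most 0.0159 over 600 distances examined. These correlations run over all features, so they cannot exclude a small patch. At the left edge of inferred rows within that first 10%, some features were raised on control array 1 alone. Control array 2 and all tumours had the shared value there. Some of these features were called lower in tumours and others missed the threshold. How many of the 188 such calls on features at the shared value on control array 2 lie there was not counted.

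Setting each of the 4 samples apart from the other 3 gave 4699 called features for the control pool and 0 for each tumour (limma, adjusted p under 0.05), with 579 to 1248 features at an unadjusted p under 0.05 for the tumours in the same moderated test. The real split was thus 1 of 4 splits with as many calls, and 4 splits are too few for a share under 0.05. In the splits that set a tumour apart, the control pool is grouped with the other tumours, so its difference from them enters the error. Their 0 calls therefore say little about the real split.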
